A study of Mus musculus and Meriones unguiculatus with 4 samples.

How the data were processed

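RNA was measured in the enamel knot region of mandibular tooth germs from wild-type mouse embryos at embryonic day 13 and wild-type gerbil (Meriones unguiculatus) embryos at embryonic day 15. Each species had 2 samples, which makes 4 libraries in all. Per the labels' protocols, tooth germs were fixed in paraformaldehyde and frozen-sectioned, the region was cut out by laser microdissection, RNA was extracted with TRIzol, and libraries were made with a SMARTer mRNA-Seq kit. The region is described as the enamel knot, and no marker used to choose it is given in the sources used here. How many animals went into a sample is likewise not given, so the spread between the 2 samples of a species may be technical.

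The submitters' processing notes name cutadapt 2.8, STAR 2.7.1a and RSEM 1.3.1 and the mouse builds GRCm38 and mm10, without saying which step made which table. The gerbil genome build is not given in the sources used here. The mouse values are FPKM per assembled locus, deposited by the authors as a table of 27632 loci that carry Ensembl mouse gene IDs, gene names and positions. The gerbil values are TPM per gene, deposited by the authors as a table of 25745 genes that carry Ensembl gerbil IDs and names. A further 4 per-sample columns of the gerbil table, which hold read counts and RPKM, were not used here. The depth of the mouse libraries is unknown and that of the gerbil libraries was not analysed here, and no interval or detection limit that needs depth is given. The 2 tables were normalized separately by the authors.

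The columns show the species but not the sample number, so each column was used as an unnumbered sample of its group. They are named here by the part of the column name that sets them apart, PEK and SEK for mouse and E21 and E23 for gerbil. The labels do not explain these endings, and E21 and E23 differ from the embryonic day 15 of the labels. If they name different stages or regions, the 2 libraries of a species are not replicates, and each SD and SE then includes that difference.

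Genes were matched by symbol, ignoring case, using symbols that occur once in each table and leaving out LOC, Gm and Rik names, which gave 13325 matched genes. The reference symbol for the mouse ID equalled the table's symbol for 13129 of the 13141 matched genes with an Ensembl mouse ID. Each library was rescaled to 1000000 over the matched genes, and these rescaled values are called levels. Log2 levels were taken as log2(level + 1), so a difference understates the change of low genes. Genes with a mean level of at least 1 over the 4 libraries and with a transcript length were kept, which left 10162 genes. Transcript length was the exon union of the GENCODE M21 basic annotation of GRCm38, and 99.9% of the mouse loci with an ID in that annotation overlapped their gene there.

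In each library, the running median of the deviation from the gene's mean over the libraries was computed along transcript length in 40 bins and subtracted. This length correction was chosen after the trend had been seen in the data, and the values without it are given where they end or make a call of a named gene. The difference between species is the mean corrected log2 level in gerbil minus that in mouse, with a standard error from the 2 libraries per species. A gene is called higher in a species when both of its libraries lay at least 2-fold above both libraries of the other species on the corrected scale. No significance test was run across the tables, since they were normalized separately, and an exact permutation of 2 against 2 libraries could not give a two-sided p below 0.333. The design fixed before the data were examined assumed counts for both species and a count model. Because the mouse table holds FPKM, the levels are described with the rule above.

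The 20 gene lists were fixed before the data were examined. A list's median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, and the percentile describes these libraries only. A median outside the central 95% of the random lists is reported as standing apart. Correlations between libraries are across genes, which are not independent replicates.

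The rule for named genes was also fixed before the data were examined. It takes all measured members of the enamel knot and BMP lists, 2 members per direction from every other list, the 10 genes with the largest difference in each direction among genes at a mean level of 10 or more in each species, and the 5 most abundant rows of each table. The rule as fixed ranked members of the other lists by adjusted p and set the minimum of 10 on counts. As there was no test and no count for mouse, members were ranked by the gap between the nearest libraries of the 2 species and the minimum was set on levels. High members that were not called are named as counterexamples. Genes chosen outside this rule are said to be so, and some genes that the rule names are not reported here.

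The procedure was tested on simulated libraries of 10059 genes with the length trends and spread of the real ones. Of 50 genes raised by 2 on the log2 scale in gerbil, 88.0% were called higher in gerbil, and of 50 lowered by 2, 90.0% were called higher in mouse. At a change of 3, all 50 were called in either direction. The raised and lowered genes were picked above a minimum expression level. Their recovery rates therefore do not describe genes at low levels, which the rule also calls. Of 9859 unchanged genes, 0.406% were called. Noise from the separate tables and gene models was not simulated, nor were unusually large differences of single genes between libraries. These rates may therefore not hold for the real libraries. Of 100 lists drawn at random from the real genes, 94 lay inside the central 95% of their random lists. Both came from the same genes, so this checks the calculation only. Lists of genes that vary together were not tested, and their medians may spread more.

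Alternatives were another pseudocount, no filter on low values, no length correction, a minimum level in each species, each library left out in turn, removal of a GC trend as well, no centring, summed loci of a mouse gene and a wider gap. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.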

Results

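Gene expression was measured by RNA sequencing in the enamel knot region of mouse and gerbil tooth germs, with 2 libraries per species. The enamel knot is a signalling centre of the dental epithelium, and the design sets the mouse region against the gerbil region, with Bmp4, cell proliferation and apoptosis as the named themes. After matching by symbol, 10162 genes were measured in both species. The depth of the mouse libraries is unknown and that of the gerbil libraries was not analysed here. Levels are rescaled to a sum of 1000000 over the matched genes and set across tables that the authors normalized separately. They are printed without the length correction, while log2 differences carry it unless said otherwise. A ratio of printed levels can therefore differ from the log2 difference beside it. Without any correction, the gerbil to mouse ratio rose with transcript length, from a median log2 difference of -1.80 in the shortest 1017 genes to 1.43 in the longest 1017, and this trend was removed from each library before genes were compared.

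**Figure D1:**
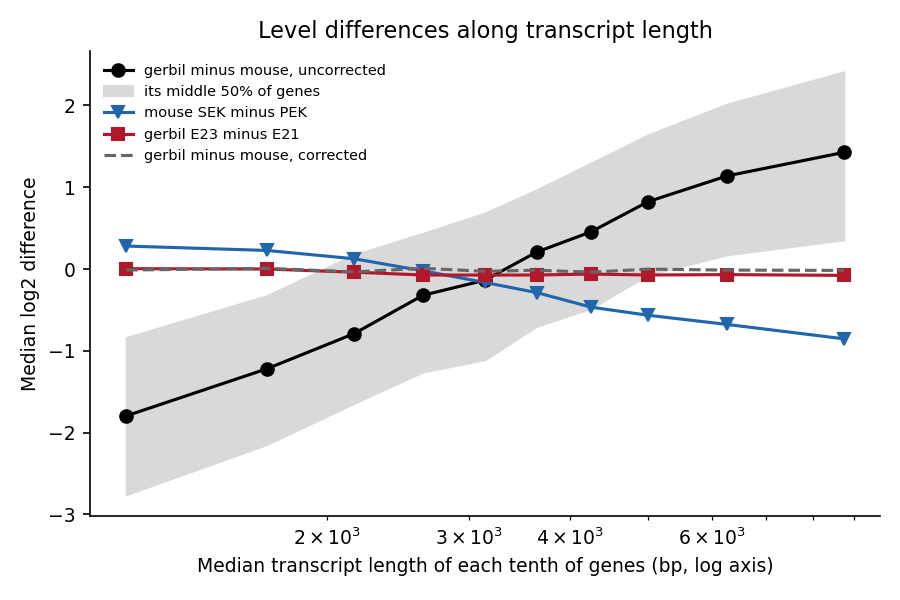
Median log2 difference in 10 classes of the 10162 measured genes by transcript length (bp, log axis), for gerbil minus mouse before and after the correction and between the libraries of each species. Before the correction the gerbil minus mouse median climbs from -1.80 to 1.43 and the SEK minus PEK median of mouse falls from 0.28 to -0.85, while the E23 minus E21 median of gerbil stays between -0.08 and 0.00.

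Enamel knot signals were on balance lower in gerbil than in mouse, while Shh, the hedgehog ligand that marks the knot, stood at similar levels. Lists of other origin moved the same way, with medians of -1.49 for stress and handling genes and -1.49 for muscle genes. Shh was 1074 ± 157 in gerbil and 777 ± 238 in mouse (SD, n = 2 each, if the unexplained library names do not stand for different stages or regions), a corrected log2 difference of 0.03 ± 0.32 (SE; -0.14 without the length correction). Cdkn1a, which encodes the cell cycle inhibitor p21 and marks the non-dividing knot, was 48.5 ± 16.2 in gerbil and 1292 ± 386 in mouse, a 33.5-fold corrected difference (log2 -5.07 ± 0.41). The Wnt ligands Wnt10a (log2 -3.55 ± 0.21) and Wnt6 (-2.68 ± 0.32) and the growth factor gene Fgf4 (-2.84 ± 0.74) were also higher in mouse. Sp6, a transcription factor of dental epithelium, was the 1 list member higher in gerbil, at 315 ± 60.9 against 14.0 ± 3.05 (log2 3.44 ± 0.39).

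Of the 18 measured enamel knot signals, 6 were higher in mouse, 1 was higher in gerbil and 11 met neither criterion. The list's median log2 difference was -1.20, at the 0.11 percentile of random lists of the same size and expression. Fgf20, which encodes a growth factor of the knot, was at 454 and 31.8 in the mouse PEK and SEK libraries, at 5.65 in gerbil E21 and listed at 0 in gerbil E23. Fgf9 was higher in mouse with a log2 difference of -1.06 ± 0.04, but the call ended without the length correction (-0.54), and with neither centring nor correction the difference was 0.10. Bmp7 (-0.94 ± 0.25), Lef1 (-1.24 ± 0.73), Wnt10b (-1.27 ± 0.79), Wnt3 (-0.87 ± 1.42) and Slit1 (-2.37 ± 1.21) met neither criterion, as did the BMP antagonist gene Sostdc1 (0.05 ± 1.11, and -1.08 without the length correction) and the Wnt antagonist gene Dkk4 (0.18 ± 1.74, and -1.45). Leaving out 1 library made calls of its own among these genes, all higher in mouse. Without gerbil E21 they were Bmp7 (-1.22), Slit1 (-2.82) and Wnt10b (-1.73), and without mouse SEK they were Bmp2 (-3.17), Fst (-3.90), Lef1 (-1.91), Slit1 (-3.52), Wnt10b (-1.97) and Wnt3 (-2.23). The Fgf9 call ended without mouse SEK (-1.01), and Fst was also called without gerbil E23 (-2.76) and with GC also removed (-2.82). Within a library, on levels without the length correction, the Cdkn1a to Shh ratio was 0.0623 and 0.0313 in gerbil E21 and E23 and 1.65 and 1.67 in mouse PEK and SEK. The Wnt10a to Shh ratio was 0.0744 and 0.0490 in gerbil and 0.786 and 1.01 in mouse. The Bmp2 to Shh ratio did not separate the species, at 0.0400 and 0.0105 in gerbil and 0.138 and 0.00901 in mouse.

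**Figure D2:**
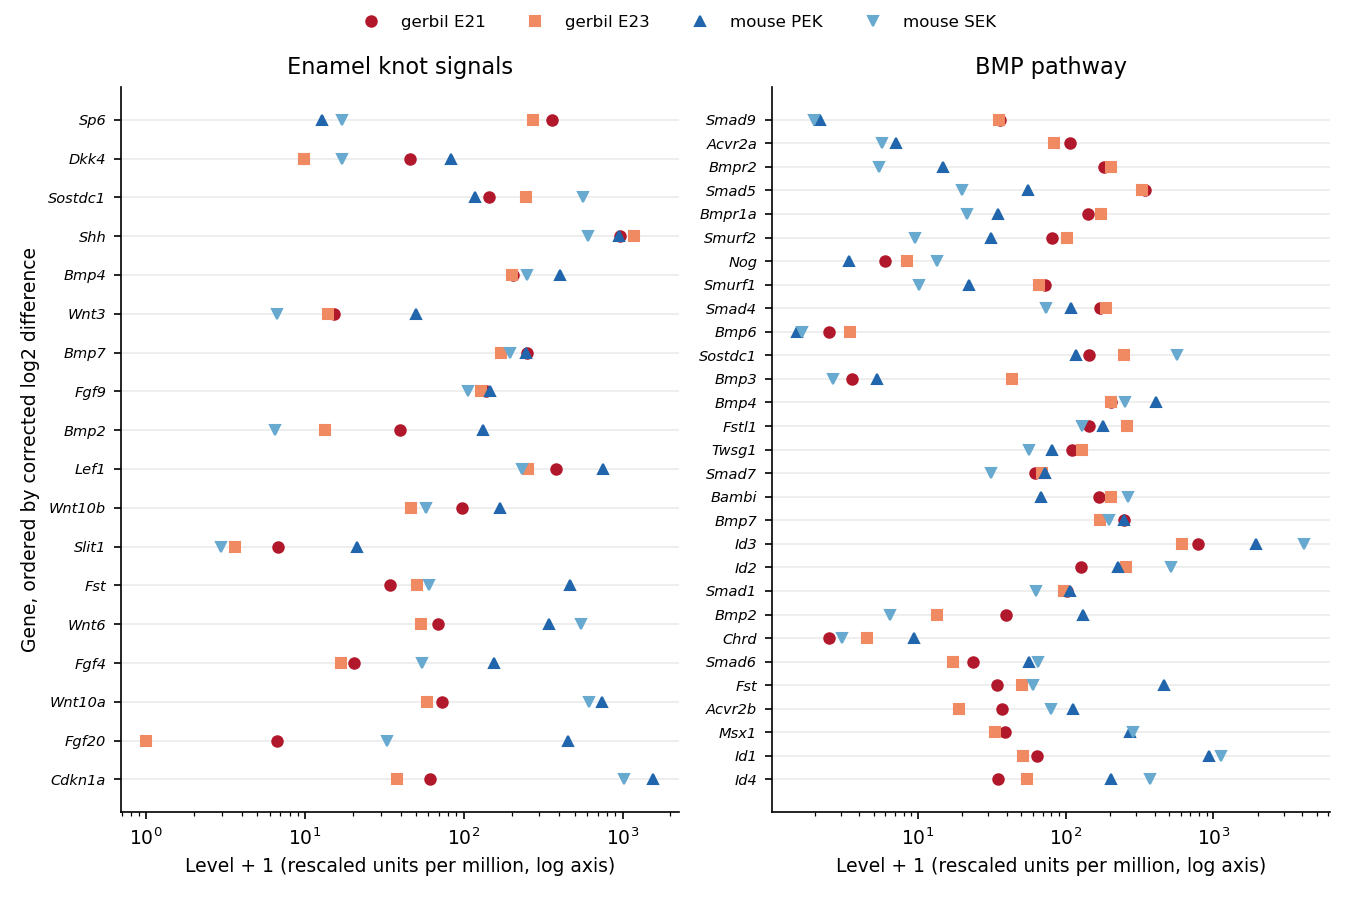
Levels plus 1 (rescaled to a sum of 1000000 over the matched genes, log axis) of the 18 enamel knot signals and the 29 BMP pathway genes in the 4 libraries, 1 point per library, ordered by the corrected log2 difference. Cdkn1a lies at 60.0 and 37.1 in gerbil against 1565 and 1019 in mouse, and Shh between 609 and 1186 in all 4 libraries.

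Bmp4 itself was not called different between the species. It was 202 ± 1.40 in gerbil and 328 ± 109 in mouse (SD, n = 2 each), with a corrected log2 difference of -0.48 ± 0.42, and without the length correction it was called higher in mouse (-1.29). The Bmp4 to Shh ratio within a library, on levels without the length correction, was 0.211 and 0.169 in gerbil and 0.428 and 0.411 in mouse. Id1, which encodes an inhibitor of differentiation, was higher in mouse, at 56.6 ± 8.54 in gerbil and 1032 ± 129 in mouse (log2 -3.03 ± 0.17). Id4 (-3.62 ± 0.66), the homeobox gene Msx1 (-2.67 ± 0.14) and the inhibitory Smad gene Smad6 (-2.06 ± 0.25) were higher in mouse too, while Id2, Id3, Bambi and Smad7 were not called. Of the receptor and Smad genes, 4 were called higher in gerbil, and others were higher in mouse or not called. Bmpr2 was at 192 ± 14.8 against 9.06 ± 6.51 (log2 2.13 ± 0.30), Acvr2a at 2.21 ± 0.22, Smad9 at 2.44 ± 0.26 and Smad5 at 334 ± 11.4 against 36.7 ± 25.4.

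Of the 29 measured BMP pathway genes, 4 were higher in gerbil, 6 were higher in mouse and 19 met neither criterion. The median log2 difference of -0.60 was at the 3.98 percentile of random lists and did not stand apart. It stood apart with a pseudocount of 0.1 (-0.72, 2.12 percentile), with no filter on low values (-0.64) and with GC also removed (-0.66). It did so too without gerbil E23 (-0.80) and without mouse SEK (-0.57). With the minimum of 10 in each species the median was -0.81 and stood apart (0.83 percentile). That minimum drops Bmpr2, Acvr2a and Smad9, called higher in gerbil, for their low mouse levels, but no member called higher in mouse. The lower median there follows in part from the filter. The receptor gene Acvr2b (-2.66 ± 0.47) and Smad1 (-1.16 ± 0.10) were higher in mouse, although the Smad1 call ended without the length correction (-0.35) and its difference was 0.28 with neither centring nor correction. The Smad5 call ended when a GC trend was removed as well (1.13). Bmpr1a (0.85 ± 0.19), Smad4 (0.17 ± 0.13), Id2 (-1.06 ± 0.77), Id3 (-0.99 ± 0.41), Bambi (-0.93 ± 1.28) and Nog (0.63 ± 0.88, and -0.57 without the length correction) met neither criterion, although Id3 was called higher in mouse without the length correction (-2.67) and Bmpr1a higher in gerbil (1.89). The antagonist gene Fst was at 33.3 and 49.6 in gerbil and at 465 and 59.2 in mouse PEK and SEK (-2.47 ± 1.45). Among the other members, Id2 (-1.67), Id3 (-1.38) and Bambi (-2.25) were called higher in mouse and Smurf2 (1.29) higher in gerbil without mouse PEK. Chrd (-2.27), Smad7 (-1.20) and, toward gerbil, Nog (1.49) were called without mouse SEK, and Bmp3 (-1.99), Chrd (-2.01) and Id2 (-1.63) without gerbil E23. Bmp3 was called higher in gerbil without gerbil E21 (1.75). Smurf1 was called higher in gerbil without the length correction (1.57), and Smurf2 with no centring either (2.39). Msx2, another homeobox gene, was at 236 and 286 in gerbil E21 and E23 and was split over 2 mouse loci, at 8.15 and 164 in PEK and at 6.51 and 529 in SEK, so no difference is given for it. In GRCm38 coordinates of the mouse table, Bmp4 (ENSMUSG00000021835) spans positions 46383513 to 46390669 of chromosome 14 and Id1 (ENSMUSG00000042745) positions 152736251 to 152737410 of chromosome 2. Shh (ENSMUSG00000002633) spans 28456810 to 28467256 of chromosome 5 and Cdkn1a (ENSMUSG00000023067) 29090979 to 29100722 of chromosome 17.

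Proliferation genes went both ways, and inhibitors of the cell cycle were on balance lower in gerbil, as was the stress and handling list (median -1.49). Mki67, which encodes the proliferation marker Ki-67, was 478 ± 119 in gerbil and 25.1 ± 10.3 in mouse (log2 2.00 ± 0.23, and 3.60 without the length correction). The replication gene Pcna was 505 ± 23.7 against 154 ± 34.2 (2.52 ± 0.08). The mitotic kinesin gene Kif11 was higher in gerbil as well (2.20 ± 0.16). Mki67 is named outside the rule for named genes, as a standard marker, after its values were seen. In contrast, Ccnd2, encoding cyclin D2, was higher in mouse at 3497 ± 1477 against 368 ± 89.9 (-5.06 ± 0.24), as was the thymidylate synthase gene Tyms (-2.98 ± 0.73). Among genes of cell cycle exit, Cdkn1c (p57) followed Cdkn1a with a log2 difference of -3.47 ± 0.47, while Cdkn1b (p27) was higher in gerbil (2.76 ± 0.56).

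Of the 36 measured proliferation genes, 5 were higher in gerbil and 4 in mouse, with a median log2 difference of 0.30 at the 97.3 percentile of random lists, inside their central 95%. Without the length correction that median was 0.28 and stood apart (99.5 percentile), and the Pcna call ended (1.09). Against random lists matched on length instead of expression, this uncorrected median was at the 80.3 percentile and did not stand apart. The median also stood apart with no filter on low values (0.41) and with the minimum of 10 in each species (0.37). It did so without gerbil E23 (0.34) and without mouse SEK (0.69). With neither centring nor correction (0.91) it stood apart from random lists that were again not matched on length. Highly expressed members that were not called include Top2a (-0.74 ± 0.20, and 0.13 without the length correction) and Cdk1 (-1.58 ± 0.78). Of the 15 cell cycle exit genes, 2 were higher in gerbil and 4 in mouse, and the median of -0.89 stood apart at the 1.70 percentile. It no longer stood apart without gerbil E21 (-0.71), without mouse PEK (-0.72), without mouse SEK (-0.60) or with the minimum of 10 in each species (-0.38). That minimum drops Cdkn2b and Gadd45b (named outside the rule), called higher in mouse, for their low gerbil levels. It drops no member called higher in gerbil. The Tob1 call (1.67 ± 0.12) ended without the length correction (1.01).

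Genes of apoptosis showed no shift as groups. The p53-inducible cell death gene Bbc3 was higher in mouse, at 47.0 ± 23.6 against 1.32 ± 0.0581 in gerbil (log2 -3.84 ± 0.62), as was Bad (-1.89 ± 0.44). Bak1, encoding a pore-forming member of the Bcl-2 family, was higher in gerbil (2.13 ± 0.59), as was the death receptor adaptor gene Fadd (1.67 ± 0.29). Among protective genes, Cflar (-2.78 ± 0.23) and Mcl1 (-1.69 ± 0.13) were higher in mouse and Birc2 was higher in gerbil (1.41 ± 0.32). With neither centring nor length correction the Cflar (-0.83) and Mcl1 (-0.94) calls ended. Trp53 met neither criterion (-0.10 ± 0.51). Of the 24 genes that promote apoptosis, 2 were higher in gerbil and 4 in mouse (median -0.19, 19.7 percentile), and of the 12 that oppose it, 1 and 4 (median -0.54, 10.4 percentile). The promoting list stood apart without the length correction (-0.63, 2.44 percentile), under which the Bak1 call ended (1.55). Against random lists matched on length instead of expression, that uncorrected median was at the 40.3 percentile and did not stand apart. The Bad and Birc2 calls ended with GC also removed (-1.38 and 1.18).

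Receptors and targets of other epithelial pathways differed gene by gene. Ptch1, the Shh receptor gene, was 356 ± 14.9 in gerbil and 33.7 ± 18.2 in mouse (log2 1.53 ± 0.19). The Wnt receptor gene Fzd10 (3.25 ± 0.87) and Lgr4 (2.69 ± 0.56), which encodes an R-spondin receptor, were higher in gerbil, and the Wnt target gene Sp5 was higher in mouse (-5.33 ± 1.35). Notch2 (1.56 ± 0.53, not called without gerbil E23 at 0.99 or with a pseudocount of 0.1 at 1.49) and the Notch effector gene Rbpj (1.72 ± 0.30) were higher in gerbil and Mfng was higher in mouse (-3.72 ± 0.75). Traf6 was the 1 called member of the Eda and NF-kB list (1.57 ± 0.15, higher in gerbil). In the Fgf list, Fgfbp1 was higher in mouse (-3.40 ± 0.85) and Fgf8 in gerbil (2.60 ± 1.07), although the Fgf8 call ended without the length correction (1.03). Ctnnb1, encoding beta-catenin, was at 2225 or more in gerbil and 1234 or more in mouse and met neither criterion (-0.14 ± 0.31, and 0.06 without the length correction).

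As groups, these pathways did not stand apart. The Shh list of 13 measured genes had a median of 0.03 (49.6 percentile). The Wnt list had 5 genes higher in gerbil and 4 in mouse of 33 (-0.17, 28.7 percentile) and the Fgf list 1 and 4 of 19 (-0.30, 26.1 percentile). The Eda and NF-kB list had 1 and 0 of 11 (-0.47, 16.4 percentile) and the Notch list 2 and 1 of 15 (0.21, 64.9 percentile). Without the length correction the Fgf (0.17) and Eda and NF-kB (0.27) medians turned positive. Without mouse SEK, the Wnt median was -0.69 and stood apart (0.37 percentile), and with GC also removed the Notch median was 0.76 and stood apart (97.7 percentile).

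Junction and actomyosin genes were on balance higher in gerbil. Vcl, which encodes the adhesion protein vinculin, was 284 ± 24.5 in gerbil and 6.82 ± 3.87 in mouse (log2 3.72 ± 0.24), and the actin gene Actg1 was 4932 ± 230 against 1752 ± 34.8 (1.76 ± 0.12). Cldn4 (-2.18 ± 0.27) and the myosin light chain gene Myl12a (-2.07 ± 0.06) were higher in mouse. Of 28 measured members, 7 were higher in gerbil and 2 in mouse, and the median of 0.61 stood apart at the 99.7 percentile, though not without mouse SEK (0.48, 95.9 percentile). The Actg1 call ended without the length correction (0.86).

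Markers of cell types went both ways between the species. In the dental epithelium list, Sp6 and Krt19 (3.29 ± 0.36) were higher in gerbil and Tbx1 (-4.00 ± 0.69) and Dlx2 (-3.83 ± 0.33) in mouse, while Krt14 (-0.34 ± 0.30) and Epcam (-0.70 ± 0.07) met neither criterion. That list had 7 genes higher in gerbil and 4 in mouse of 22 (median -0.12, 56.6 percentile). Tnc, encoding the matrix protein tenascin C and placed in the dental mesenchyme list, was at 1880 and 500.2 in gerbil E21 and E23 and at 5.05 and 2.72 in mouse PEK and SEK (5.74 ± 0.88). Alcam was higher in gerbil (3.09 ± 0.43), Inhba (-3.72 ± 0.79, not called with neither centring nor correction at -1.85) and Msx1 in mouse, and the mesenchyme list had 2 and 3 calls of 25 (-0.24, 22.2 percentile, and 0.59 without the length correction). Muscle genes were higher in mouse in 3 of 10 cases and in gerbil in 0, with a median of -1.49 at the 1.20 percentile, though not apart without mouse SEK (-1.19, 9.13 percentile). Mylpf, a fast muscle myosin light chain gene, was at 66.8 and 257 in mouse PEK and SEK, at 2.63 in gerbil E23 and listed at 0 in E21, and Myh3 was higher in mouse at under 3 units (-3.15 ± 0.47).

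Lists of other tissues did not stand apart between species. The endothelium list had 0 calls of 8 (median 0.07, 59.4 percentile) but stood apart when gerbil E21 was left out (1.76, 98.4 percentile) and, on the other side, when gerbil E23 was left out (-1.86, 2.00 percentile). The blood and immune list had 1 call of 8, C1qa, higher in gerbil (2.08 ± 0.77, list median 1.13, 96.3 percentile), which ended without the length correction (0.36). Without the correction the blood and immune median was -0.04 and the endothelium median -0.05. Alpl (3.26 ± 1.37) was higher in gerbil in the bone and cartilage list (1 call of 7, median -0.44, 24.8 percentile). In the neural and Schwann cell list, Stmn2 was higher in mouse (-3.38 ± 0.53), and the 4 measured members had a median of 0.03 (46.1 percentile).

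Of 11 measured genes that respond to stress or handling, 6 were higher in mouse, 0 in gerbil and 5 met neither criterion. Ier2, an immediate-early gene, was 411 ± 37.9 in mouse and 2.60 ± 0.910 in gerbil (log2 -6.07 ± 0.41), and Egr1 was 27.1 ± 18.4 against 3.36 ± 1.98 (-3.75 ± 0.69). The median of -1.49 stood apart at the 0.17 percentile. The heat shock gene Hsp90aa1 was an abundant exception (0.70 ± 0.20). The list did not stand apart when GC was also removed (-0.82, 3.36 percentile) or with the minimum of 10 in each species (-0.17, 44.2 percentile). That minimum drops Ier2 and Egr1 for their low gerbil levels, so the smaller median there follows in part from the filter.

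**Figure D3:**
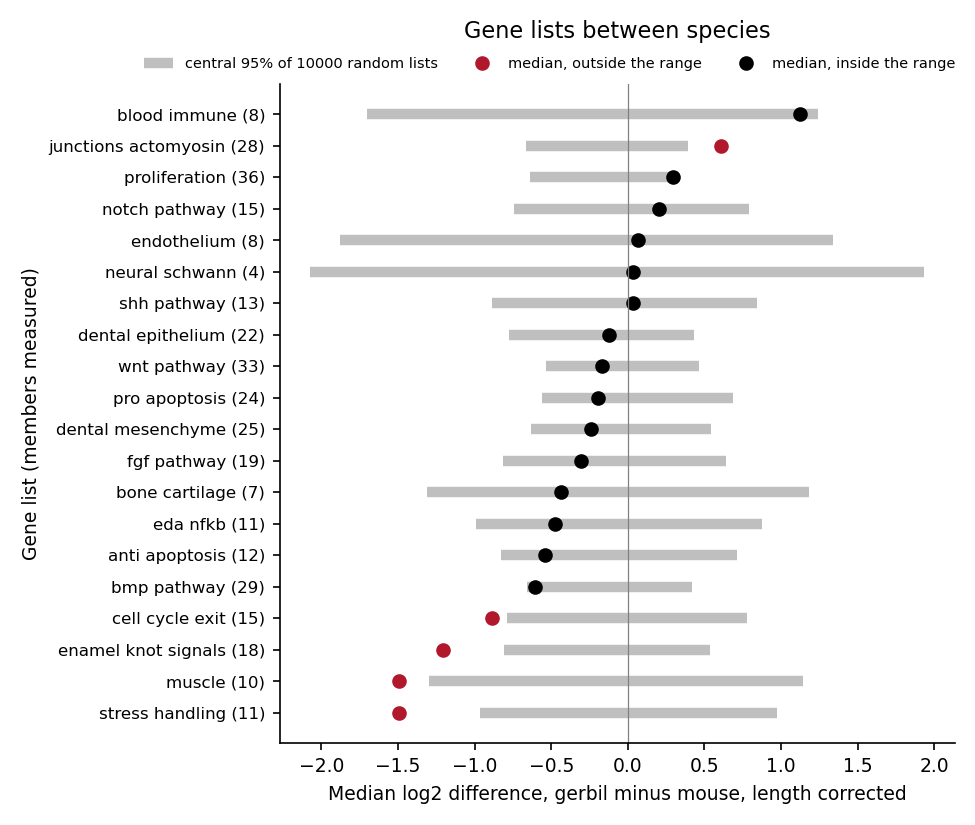
Median corrected log2 difference, gerbil minus mouse, of the 20 gene lists (points, with the number of members measured) and the central 95% of 10000 random lists matched on size and expression (bars). The junction list lies above its bar at 0.61, and the cell cycle exit (-0.89), enamel knot (-1.20), muscle (-1.49) and stress (-1.49) lists lie below theirs.

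Over all genes, 1358 were higher in gerbil and 1492 were higher in mouse. The largest differences toward gerbil, among genes at 10 or more in each species, were in Polr2l, which encodes a small RNA polymerase II subunit (580 ± 94.4 against 42.3 ± 9.67, log2 4.34 ± 0.17), Zfp146 (4.31 ± 0.47) and the transporter gene Slc4a11 (4.24 ± 0.91). They were followed by Ipp (3.69), Tagln (3.65), Cox7a1 (3.61, not called without the length correction at 1.45), Nsdhl (3.55), Sp6, Krt19 and Scarb2 (3.29). Toward mouse they were in Lars2 (-8.42 ± 0.79), Cmss1 (-6.85 ± 1.71), Ucp2, an uncoupling protein gene (893 ± 110 against 16.1 ± 4.81, -6.74 ± 0.41), Tonsl (-5.91 ± 0.42) and Ccdc85b (-5.53 ± 0.46). Next came Ulk4 (-5.27), Basp1 (-5.07), Cdkn1a, Smyd3 (-5.06) and Ccnd2. Lars2 and Cmss1 were at 17086 and 35567 in mouse PEK and at 4850 and 4429 in SEK, and their values are uncertain, since reads shared with other sequences were not excluded. The other 2 ways to split the 4 libraries into pairs gave 97 and 26 genes by the same rule. At any gap, 74.3% of genes had species that did not overlap, where 33.3% would be the share if the 4 libraries were exchangeable. They were not, since each species has its own separately normalized table and gene models. A difference between the tables would separate the species too, so these counts do not show how much is due to species. With neither centring nor length correction, 3021 genes were higher in gerbil and 1209 in mouse, around a median log2 difference of 0.62 over all genes.

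In the whole tables, the most abundant gerbil rows were the signal recognition particle RNA Metazoa_SRP at a mean of 318630 TPM, 2 rows of 7SK at 74902 and 72306 TPM, an unnamed mitochondrial rRNA at 65350 TPM and U1 at 35604 TPM. The 5 highest mouse rows were a Parp9 locus and 4 unnamed loci, all with FPKM above 1000000, and none of the 10 rows entered the comparison.

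The libraries of a species resembled each other more than those of the other species, but differed in several knot signals. Across genes, Pearson's r of log2(value + 1) was 0.980 for gerbil (Spearman's rho 0.970, 16498 named rows) and 0.961 for mouse (0.957, 20513 named rows). Between species, r of corrected levels lay between 0.729 and 0.756, against 0.952 within gerbil and 0.930 within mouse on the same genes. Bmp2 was at 131 in mouse PEK and 5.49 in SEK, and at 38.5 in gerbil E21 and 12.4 in E23. Dkk4 was at 81.6 and 16.0 in mouse PEK and SEK and at 45.0 and 8.92 in gerbil E21 and E23. The enamel knot list was lower in SEK than in PEK (median log2 -1.06, 0.00 percentile) and lower in E23 than in E21 (-0.35, 0.05 percentile). Setting SEK beside E23 is 1 of 2 possible pairings, and the labels give no reason for either.

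Other lists differed between the libraries too. Endothelial genes were higher in E23 than in E21 (median 4.15), with the endothelial receptor gene Kdr, chosen after its values were seen, at 32.3 against 0.302, and higher in SEK than in PEK (1.12, 99.7 percentile). Muscle genes were higher in SEK (0.94) and in E23 (0.89), and proliferation genes were higher in SEK (0.65) and lower in E23 (-0.22). The labels call these libraries samples of 1 group, and each within-species difference rests on 1 library against 1, with no replicate check.

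**Figure D4:**
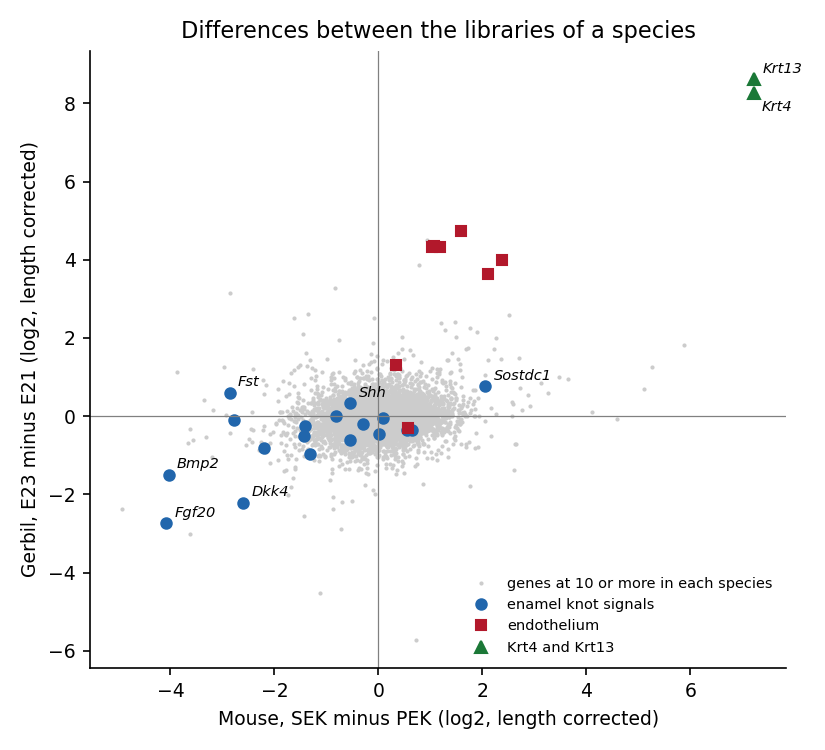
Length-corrected log2 difference between the libraries of a species, mouse SEK minus PEK on the x axis and gerbil E23 minus E21 on the y axis. Grey points are genes at 10 or more in each species. Enamel knot signals, endothelial genes and the keratin genes Krt4 and Krt13 are marked without that minimum. Some marked genes were therefore low, such as Fgf20 at a mean level of 2.83 in gerbil. Krt13 lies at 7.23 and 8.63, Bmp2 at -4.03 and -1.49, and Shh at -0.54 and 0.34.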

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

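Both signals below were chosen for mention after the data were seen. Small RNA classes took 69.2% of the gerbil TPM in E21 and 72.5% in E23, a signal that the comparison between species does not use. Among the loci of mouse, 64 had an FPKM above 1000000 in at least 1 library, and 63 of them carried no gene name and so could not be matched.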

How the results depend on the processing

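Removing a GC trend, leaving out centring, summing loci and the 4-fold gap were chosen after the data were seen. Over all settings but the minimum level and the wider gap, the count of genes apart lay between 2595 and 4230, against 2850. With each library left out in turn it ranged from 3531 to 3980 (1666 to 1935 higher in gerbil, 1865 to 2045 in mouse), which follows from fewer libraries having to agree. With the minimum of 10 in each species it was 1409 (663 and 746), which follows from fewer genes, and with a 4-fold gap 874 (319 and 555), which follows from the stricter rule. With neither centring nor length correction, 3021 were higher in gerbil, 71.4% of calls against 47.6%. Without the length correction 2045 of the 2850 calls remained, and with a GC trend also removed 2214.

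The number of lists standing apart was 5 of 20, where 1 would be expected of random lists. It was between 4 and 7 over the settings other than leaving out a library and the 4-fold gap, which does not bear on it. With a library left out it ranged from 4 to 8. The 8 came without gerbil E23, where the BMP, proliferation and endothelium lists stood apart as well, and the cause was not tested. With a library left out, the endothelium median ranged from -1.86 to 1.76 and Bmp3 from -1.99 to 1.75, called toward mouse without gerbil E23 and toward gerbil without E21. Of 76 called named genes, 49 were called with the 4-fold gap and 51 with the minimum level, which drops 28 named genes, and from 66 to 76 were called under the other settings. Fgf9 (0.10) and Smad1 (0.28) turned positive with neither centring nor correction, which adds the overall median of 0.62. Within-species r stayed between 0.917 and 0.980. No paired analysis was possible because the columns carry no replicate number and no test was run. The planned count models, size factors, length matching between tables and limma, camera and fry tests were not run, since the tables were normalized separately and counts were not used here. No limit set by depth was analysed here.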

Other observations

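Surface keratin genes were among the largest differences between libraries of the same species. Krt13 was listed at 0 in gerbil E21 and was at 396 in E23, and it was at 0.492 in mouse PEK and at 274 in SEK. Krt4 followed the same course, listed at 0 and at 304 in gerbil and at 0.511 and 238 in mouse. Gpx3, S1pr1, the carbonic anhydrase gene Car2, Plac8, Lum, Emb, Lrrtm1 and Ctsk were likewise higher in SEK and in E23, and Dusp26, Gad1, Dkk4, Ascl4, Ajap1, Gfra1, Bmp2, Dpysl5, Spred3 and Kremen2 were lower in both. These genes were chosen after their values were seen, as the 10 in each direction whose smaller difference of the pair was largest.

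The tests below on length in the mouse libraries, on Shh, on the knot list without correction and on p53 targets were chosen after their results had been seen.

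The gerbil to mouse ratio rose with transcript length (Spearman's rho 0.552 across genes). GC content is argued against as the whole cause, since rho was at least 0.495 in each of 3 classes of genes by GC. Untranslated regions missing from the gerbil gene models are argued against as well, since rho with coding length was 0.548 in the 3387 genes with the smallest untranslated share. A length bias of the mouse libraries may account for it: the difference between the 2 mouse libraries also followed length (rho -0.443), and that between the gerbil libraries hardly did (-0.0591). A difference between the species in long genes stays open, as untested.

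The libraries of each species differed in part in the same genes, with SEK set beside E23 as 1 of 2 possible pairings: SEK minus PEK and E23 minus E21 correlated across genes at r = 0.211 without correction, and 34 genes were at least 2-fold higher in both SEK and E23 where independent lists would share 6.71. Another 25 were lower in both (5.55 by chance), while 18 were lower in SEK and higher in E23 (6.38) and 5 the reverse (5.84). Length and GC trends are argued against, since r was 0.215 with the length trend removed and 0.210 with both removed. Oral surface epithelium in SEK and E23 is a candidate source of the Krt4 and Krt13 signal that cannot be told apart: its list, without these genes, had a median difference of 1.76 in mouse, where Krtdap went from 119 to 1462, but of 0.021 in gerbil, where Krtdap went from 0 to 11.6. Of its 24 genes, 14 were measured, 4 were at 10 or more in both PEK and E21, and 1 is in another list. The labels give the libraries of a species as 1 group, so no biological explanation other than oral surface epithelium was tested.

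Enamel knot signals and Cdkn1a were lower in gerbil. A smaller share of knot cells in the gerbil libraries cannot be told apart. It would lower Shh as well, and Shh differed by 0.031 ± 0.32. However, Shh is 1 gene of the list, and 14 members lay below it. Its level per knot cell in either species is unknown. The length trend is argued against. Without its correction the list's median was -1.24, at the 2.22 percentile, and 5 of the 6 members higher in mouse stayed so. A p53 response in the mouse libraries cannot be told apart, since the p53 targets went both ways. The list leaves out Cdkn1a, and 7 of its 21 genes are in another list. Its 18 measured members had a median of 0.24, at the 77.3 percentile, with quartiles of -0.78 and 1.14. Bbc3 (-3.84) and Aen (-3.31) were the 2 called higher in mouse, and 0 were called higher in gerbil. Handling stays open, as the stress list moved the same way (median -1.49, 0.17 percentile), and species and embryonic day, which the labels vary together, and the gene models stay open as untested.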
